A study of Homo sapiens with 3 samples.

How the data were processed

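Gene expression was measured in primary human endometrial stromal cells, the fibroblast-like cells of the uterine lining that become decidual cells before and during pregnancy. Per the labels' protocols, cultures were transduced with a recombinant adenovirus expressing GFP (green fluorescent protein, the control), BMP2 (a bone morphogenetic protein, a secreted ligand of SMAD1/5 signalling) or WNT4 (a secreted Wnt ligand) at a multiplicity of infection of 50 in 2 ml of medium. Virus was removed after 24 h and the cells received a hormone treatment named E+P (estrogen and progesterone in this field) for 3 days to induce decidualization. Each treatment was done in 3 cultures, whose RNA was pooled. Labelled antisense RNA was made from 100 ng of total RNA with a kit that primes at the 3' end of transcripts, and each pool was hybridized to 1 Affymetrix HG-U133 A 2.0 array. The series therefore held 3 arrays, 1 per group.

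The values are probe set intensities on a linear scale that the authors made with the MAS5 algorithm in Affymetrix Expression Console version 1, per the submitters' processing notes. A probe set is a group of short probes for 1 transcript or a few. Background correction and filters were not given in the sources used here, and detection calls were not used here. The deposited intensities had been scaled: the mean signal without the highest and lowest 2% of probe sets was 150.05 on the GFP and BMP2 arrays and 150.04 on the WNT4 array. No genome build applies to these values and no coordinates are given.

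The table held 22277 probe sets, of which 62 were controls. GEO's platform annotation, with symbols updated through the gene identifier, gave 1 gene for 19070 probe sets and several genes for 1043, and 2164 probe sets, controls included, were not listed in it and stay unnamed. Of the probe sets with 1 gene, 19058 were matched by identifier and 0 changed their symbol. Probe sets with several genes were not used. To protect donors, 31 probe sets of XIST, TSIX or genes found only on the Y chromosome were left out. Other genes of the X chromosome stayed in. The remaining probe sets covered 11939 genes, and 4304 of these had 2 or more probe sets. Members of gene families with near-identical sequences, such as the PSG, MT1 and keratin genes, can share signal and are uncertain as single genes.

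Signals below a floor of 16.1, the 40th percentile of all signals of non-control probe sets, were raised to the floor, and log2 was taken. Under the floor lay 38.4% of the probe sets on the GFP array, 44.2% on the BMP2 array and 37.4% on the WNT4 array. A gene was represented by its probe set with the highest mean signal and counted as measured in a comparison if it was above the floor on at least 1 of both arrays. A fold whose lower side lay at the floor is a bound and is written as "at least". With 1 array per group there is no replicate, no spread between replicates and no p-value. The number of arrays limits the precision of every value. Genes were called higher or lower by a fixed rule of size, a difference of at least 2-fold (1 in log2).

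Comparisons were BMP2 against GFP, WNT4 against GFP, BMP2 against WNT4, and the genes shared by both comparisons with GFP. For 26 gene lists, the median log2 difference of the measured members was placed as a percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A percentile below 2.5 or above 97.5 was taken to stand apart. This describes these arrays and is not a test between conditions. The lists, the rules and most alternatives were fixed before the data were examined. The genes named in a comparison with GFP are the transgenes, the 12 highest and 12 lowest genes whose probe sets all moved the same way, and list members at least 2-fold different. Genes were ranked after the floor, so the order of genes whose folds are bounds is set by it. For BMP2 against WNT4 the rule took 6 and 6 genes, and for the shared response the 6 highest and 6 lowest by the smaller of both differences, with FOXO1, whose probe sets move apart, set aside from the ranking.

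The steps were tested on simulated arrays with known changes, with noise taken from the middle of the real differences, which also hold real effects. In a simulation of BMP2 against GFP over 8429 genes, the rule found 57.8% of the genes changed 2-fold, 83.1% of those changed 4-fold and 98.4% of those changed 8-fold, and it named 20.7% of the unchanged genes. In that of WNT4 against GFP over 8140 genes, the shares were 45.5%, 87.1% and 95.3%, and 2.94% of the unchanged genes were named. Of the unchanged lists of 20 genes, 6% stood apart in the first simulation and 4% in the second. These lists were of random genes, with noise drawn independently for each probe set. Genes of a real list can move together, so these shares are not the rate for real lists.

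Alternatives fixed before the data were examined were scaling by the array median, quantile normalization, floors at the 25th and 60th percentile and no floor, the mean over all probe sets of a gene, leaving out probe sets whose names mark possible binding to several transcripts, and thresholds of 1.5-fold and 3-fold. Added after seeing the data were scaling to the hybridization controls, a count over genes whose every probe set was measured and the decidualization markers without FOXO1 and without the transgenes. 5 further gene lists were also added after seeing the data and are described among the other observations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.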

Results

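The effects of BMP2 and WNT4 on decidualizing human endometrial stromal cells were profiled on 3 arrays, 1 each for cells transduced with GFP, BMP2 or WNT4 adenovirus and then treated with hormones for 3 days. Each array carried RNA pooled from 3 cultures, so no value has a replicate. Across probe sets, log2 signals correlated at r = 0.933 between BMP2 and GFP, 0.976 between WNT4 and GFP and 0.911 between BMP2 and WNT4. The median signal was 37.1 on the GFP array, 25.9 on the BMP2 array and 40.6 on the WNT4 array. The BMP2 array also had a lower signal at the 5' ends of control transcripts. For ACTB, the ratio of 3' to 5' signal was 5.91 on the BMP2 array, 1.12 on the GFP array and 1.10 on the WNT4 array. These arrays are named below by their labels.

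**Figure D1:**
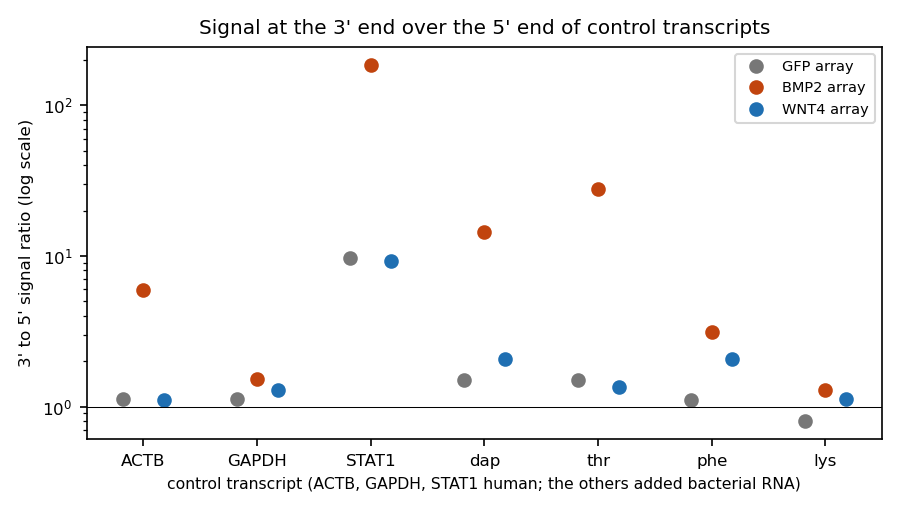
Ratio of 3' to 5' signal (log scale) of 3 human and 4 added bacterial control transcripts on each array. The BMP2 array has the highest ratio for each transcript, from 1.30 for lys to 185 for STAT1.

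The transgenes were examined first, as a check of the labels. The brighter of both BMP2 probe sets had a signal of 1129 on the BMP2 array, 62.2 on the GFP array and 88.6 on the WNT4 array, which is 18.1-fold over GFP. The other BMP2 probe set had signals of 125, 62.0 and 82.2 on these arrays, 2.01-fold over GFP. The WNT4 probe set, the only 1 named for this gene, had a signal of 31.7 on the WNT4 array and lay under the floor on the GFP array (7.30) and the BMP2 array (6.93). The WNT4 signal was thus at least 1.97-fold higher on the array labelled WNT4, just under the 2-fold rule. It also lay below the median signal of that array (40.6). This check therefore leaves the WNT4 label and the level of WNT4 overexpression unsettled. The place of these probe sets in the transcripts was not used here, and a viral sequence without untranslated regions can escape a probe set that lies in one. Genes without a transgene had probe sets further apart on the BMP2 array. In BMP2 against GFP the BMP2 gap of 3.17 in log2 ranked 31 of 2358 genes, and the widest were COL1A1 (4.93), FGFR1 (4.65) and BGN (4.52). A fold given by 1 probe set on this array can thus depend strongly on the probe set.

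The comparison of BMP2 with GFP asks which genes the ligand changes in hormone-treated stromal cells. Every group in it was measured on the array whose ratio of 3' to 5' signal was 5.91 for ACTB. Of the lists fixed before the data were examined, BMP targets lay furthest above GFP on the BMP2 array: 13 of 20 measured BMP and SMAD1/5 targets were at least 2-fold higher, 0 were lower, and the list median of 1.71 in log2 lay at the 100th percentile of random lists. HEY1, a transcriptional repressor, was 74.4-fold higher and the homeobox gene DLX2 43.5-fold. BAMBI, a decoy receptor that dampens BMP and TGF-beta signalling, was 24.4-fold higher. The inhibitors of differentiation ID1, ID2, ID3 and ID4 were 3.58-, 5.39-, 8.10- and 21.4-fold higher, and the inhibitory SMAD6 and SMAD7 were 4.84- and 11.6-fold higher. Among the ligands, receptors and SMADs of the pathway, of which 3 of 13 were higher and 3 lower, the transducers SMAD1 and SMAD5 were 3.19- and 3.09-fold lower.

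Decidualization markers were also higher on the BMP2 array: 6 of 13 measured members, including BMP2 itself, were at least 2-fold higher and 0 lower, with a median of 0.65 at percentile 99.9. Without the transgenes BMP2 and WNT4 and without FOXO1, 4 of 11 were higher, with a median of 0.60 at percentile 99.8. FOXO1, a transcription factor of decidual cells, was 8.68-fold higher, and its other probe set 4.34-fold. The cytokine IL11 was at least 7.48-fold higher, the Wnt antagonist DKK1 5.27-fold, the protease inhibitor TIMP3 3.14-fold and the proteoglycan LUM 2.18-fold. PRL, the classical secreted marker, had a signal of 24.4 on the BMP2 array and lay under the floor on the GFP array. Its difference of at least 1.52-fold did not reach the rule. IGFBP1 had a signal of 17.7 on the BMP2 array, just over the floor, at least 1.10-fold over GFP. Also short of the rule, CEBPB was 1.57-fold, SST at least 1.14-fold and IL15 1.01-fold higher. DCN was 1.16-fold and LIF at least 1.60-fold lower.

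Several Wnt components differed in both directions. The secreted Wnt antagonist FRZB was 75.0-fold over GFP, and SFRP4 and CTNNB1, which encodes beta-catenin, were 2.38- and 3.35-fold higher. The ligand WNT2 was 20.6-fold lower, and FZD6, a receptor, and TCF7L2, a transcription factor, were 3.00- and 2.61-fold lower. Of 20 measured Wnt ligands, receptors and antagonists, 5 were higher and 4 lower, and their median of 0.41 (percentile 99.4) changed sign with the floor and with the choice of probe sets. Of 11 canonical Wnt targets, 4 were higher, among them LEF1 at 3.99-fold, and 5 were lower, among them LGR5 at least 11.3-fold and MYC 7.17-fold, with a median of -0.07 at percentile 50.7.

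Some genes of muscle and of pericytes, the cells that wrap small vessels, were higher. PLN, a regulator of the calcium pump of muscle, was at least 72.4-fold higher, ACTC1, cardiac actin, 18.3-fold, and the pericyte marker RGS5 at least 24.1-fold. Of 10 pericyte and smooth muscle markers, 3 were higher and 0 lower, with a median of 0.78 at percentile 99.8, a placing that was lost (percentile 80.3) without the probe sets that may bind several transcripts. Contractile and myofibroblast genes did not stand apart, with 2 of 19 higher, 2 lower and a median of 0.18 at percentile 87.7. The remaining genes among the 12 highest were the chemokine receptor CXCR4 (at least 26.7-fold), LRRN3 (at least 24.8-fold), STMN2 (22.0-fold) and the interferon-induced IFI6 (24.0-fold).

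Interferon response genes as a group were higher, 14 of 26 by at least 2-fold and 0 lower, with a median of 1.23 at the 100th percentile. IFI27 was 8.16-fold, IFI44L at least 7.67-fold and ISG15 4.07-fold over GFP.

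Cell cycle genes were lower on the BMP2 array. Of 28 mitosis genes, 17 were at least 2-fold lower and 1, BUB1, was 2.47-fold higher, with a median of -1.54 at percentile 0. CDK1, the kinase that starts mitosis, was at least 6.40-fold lower and TOP2A at least 5.05-fold. Of 18 DNA replication genes, 9 were lower and 0 higher, with a median of -0.996 at percentile 0.02. RRM2, a subunit of ribonucleotide reductase, was at least 8.92-fold lower and TYMS, thymidylate synthase, 4.38-fold. Both placings were lost with the floor at the 60th percentile, at percentiles 18.3 for the mitosis and 2.65 for the replication genes. The ratio of 3' to 5' signal of 5.91 for ACTB belongs to the same array.

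Amino acid and stress genes were lower as well. Of 19 endoplasmic reticulum and amino acid stress genes, 8 were lower and 0 higher, with a median of -0.92 at percentile 0.01. ASNS, which makes asparagine, was 8.33-fold lower, the ATF4 target TRIB3 4.62-fold and the transcription factor XBP1 3.77-fold. The serine synthesis enzymes PSAT1 and PHGDH, among the 12 lowest genes, were at least 57.2-fold and 16.7-fold lower. Of 14 cholesterol synthesis genes, 4 were lower and 0 higher, with a median of -0.61 at percentile 2.08, which rose above 2.5 under 4 of 8 alternatives. These lower groups, too, come from the array with the ACTB ratio of 5.91.

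Other genes far lower on the BMP2 array include HSD17B2, which inactivates estradiol, at least 64.9-fold below GFP. KRT19, a keratin, was 64.5-fold lower, the imprinted gene MEST 53.9-fold, the retinaldehyde dehydrogenase ALDH1A1 50.1-fold and the chemokine receptor ACKR3 26.4-fold. CYTL1 was at least 22.3-fold lower, the adhesion molecule VCAM1 at least 17.95-fold, RGCC at least 17.9-fold and CPE, a carboxypeptidase, 16.8-fold. Of 17 inflammatory genes, 8 were lower, among them the chemokine CCL2 at 14.6-fold, and 3 higher, with a median of -0.68 whose percentile of 2.59 did not stand apart. Of 29 matrix genes, 7 were lower and 5 higher. COL6A2 was 4.02-fold and LAMA2 11.5-fold lower, and POSTN and TNC were 2.57- and 2.89-fold higher.

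In all, 8155 genes were measured in BMP2 against GFP, with 727 at least 2-fold higher and 1031 lower, or 8.91% and 12.6%. In the simulation of unchanged genes for this comparison the rule named 20.7%, close to the observed total. Its noise was taken from the middle of these same differences, so this closeness follows in part from the construction. The share therefore does not tell how many of the genes called differ through noise. Of 25 lists with a percentile, 5 stood above and 4 below random lists, and the other 16 lay between percentiles 2.59 and 87.7. Of markers of other cell types, 2 of 4 endothelial markers, FLT1 and EGFL7, were lower (median -1.02, percentile 3.87), and of 8 epithelial markers CD24 was 17.6-fold higher and KRT19 lower (median -0.25, percentile 25.6). Of the leukocyte markers, 2 were measured and 0 differed 2-fold. The split of higher and lower genes depended on the scaling, with 1878 higher and 482 lower after median scaling.

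**Figure D2:**
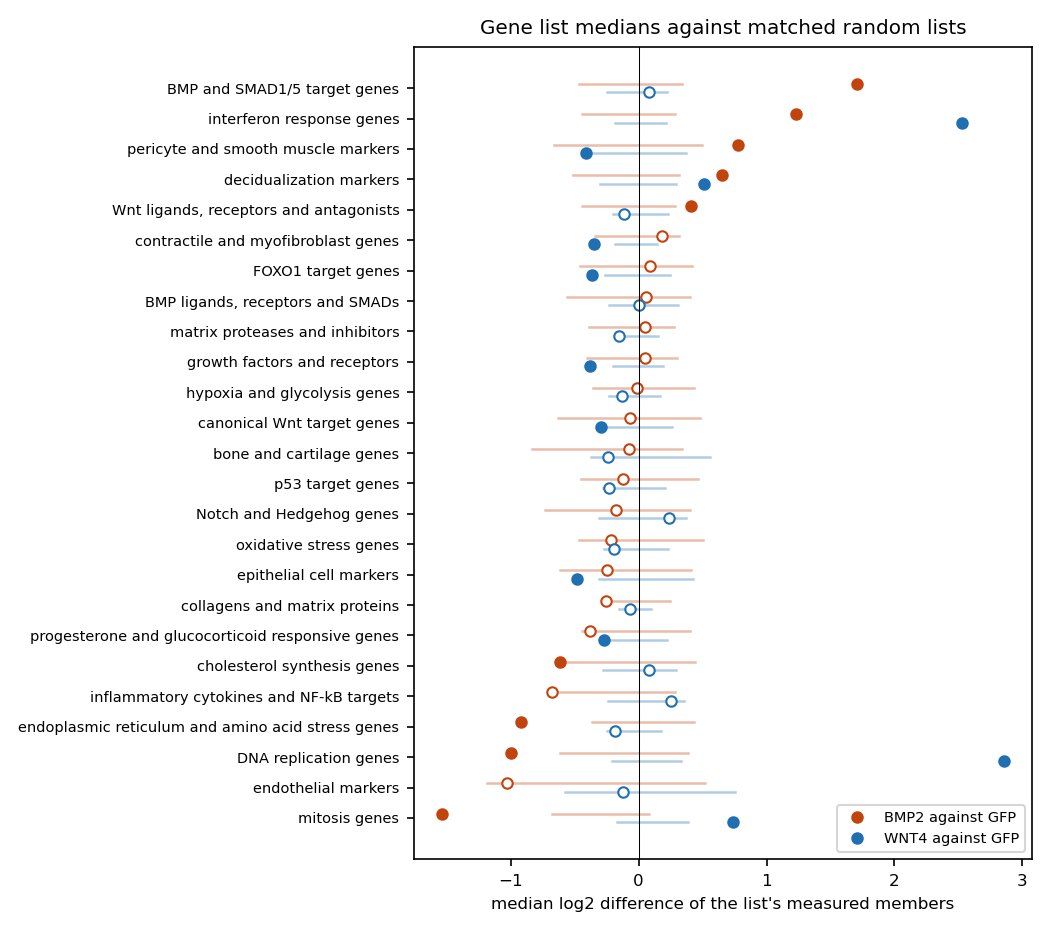
Median log2 difference from the GFP array of the measured members of each gene list (x axis), for the BMP2 array (orange) and the WNT4 array (blue). Lines span the median of 10000 matched random lists plus and minus 2 SD and filled points stand apart from them. BMP targets (1.71) and interferon genes (1.23) lie furthest right on the BMP2 array, and DNA replication genes (2.86) and interferon genes (2.53) on the WNT4 array.

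The comparison of WNT4 with GFP asks the same for the Wnt ligand. Of the lists fixed before the data were examined, DNA replication genes lay furthest above GFP: 23 of 23 measured members were at least 2-fold higher, with a median of 2.86 at the 100th percentile. CCNE2, a cyclin of S phase entry, was at least 16.4-fold higher and CDC45, part of the replicative helicase, at least 13.4-fold. TYMS and RRM2, which make DNA precursors, were 11.97- and 10.5-fold higher, and the helicase subunits MCM2 and MCM5 9.97- and 10.5-fold. The transcription factor E2F1 was at least 4.80-fold higher. Mitosis genes were higher to a smaller extent, 11 of 28, among them CDK1 at 3.19-fold and MKI67 at 2.29-fold, with KIF20A 2.30-fold lower and a median of 0.74 at percentile 100. The centromere protein gene CENPU, among the 12 highest, was 11.7-fold higher.

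Interferon response genes were higher on the WNT4 array in 20 of 28 measured members and lower in 0, with a median of 2.53 at the 100th percentile. OASL was at least 40.7-fold higher, HERC5 at least 24.0-fold and IFI44L at least 13.2-fold. The antiviral effectors IFIT2, OAS1, MX1 and IFIT3 were 12.3-, 11.3-, 10.8- and 10.6-fold higher.

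Decidualization markers had a median of 0.51 at percentile 99.9 on the WNT4 array, with 3 of 11 measured members higher, 1 of them FOXO1, and 0 lower. The WNT4 and BMP2 transgenes are members of this list. Without them the placing was lost, with 3 of 9 higher and a median of 0.14 at percentile 85.3, and without FOXO1 as well 2 of 8 were higher, with a median of 0.04 at percentile 64.8. IGFBP1, a secreted decidual marker, was at least 7.48-fold higher and the proteoglycan DCN 3.95-fold. FOXO1 was 45.6-fold higher by the probe set with the higher mean signal, with signals of 52.0 on the GFP array and 2371 on the WNT4 array. Its other probe set had signals of 116 and 62.4, 1.85-fold lower. The gap of 6.40 in log2 between these probe sets was the widest of 2663 genes with several probe sets above the floor, and the next, YWHAZ, had 2.59. No direction can be given for FOXO1 in this comparison. The median of the list left its place above random lists with the floor at the 60th percentile, at percentile 88.5.

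Other lists had small shifts on the WNT4 array. Growth factors and receptors had a median of -0.38 (percentile 0) with 4 of 21 lower, among them FGF7 and ANGPT1 at 2.12- and 2.47-fold. FOXO1 targets had a median of -0.36 (percentile 0.16), with TXNIP and CCNG2 2.23- and 2.59-fold lower and IGFBP1 higher, 3 of 15 members in all. Contractile genes had a median of -0.34 (percentile 0.05), with CNN1 and MYH11 2.01- and 2.98-fold lower among 19. The same CNN1 and MYH11 were the lower members among 9 pericyte and smooth muscle markers, whose median was -0.41 (percentile 0.84). Epithelial markers had a median of -0.48 (percentile 0.11) over 10 members, with KRT19 3.32-fold lower and EPCAM and SPINT1 at least 3.20- and 2.46-fold higher. Canonical Wnt targets had a median of -0.29 (percentile 1.27) over 13 members, with the transcription factor LEF1 3.24-fold higher and the receptor LGR5 2.27-fold lower. Progesterone and glucocorticoid responsive genes had a median of -0.27 (percentile 1.02) over 18 members, of which SGK1 was 2.02-fold lower. The Wnt target and progesterone placings, and those of the contractile, epithelial and pericyte lists, were each lost under at least 1 alternative.

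Among the genes lower on the WNT4 array, ACTC1 was 4.99-fold below GFP. PSG6, 1 of the pregnancy-specific glycoproteins, was 4.01-fold lower, TCIM 3.91-fold, the growth factor gene EGF 3.60-fold and the water channel gene AQP1 3.03-fold. B3GALT2 was at least 3.43-fold lower, RUBCNL 3.25-fold, the cytokine CTF1 3.17-fold, PADI2 3.11-fold, SERPINB7 at least 3.04-fold and TOX 2.99-fold. WNT2 was 2.36-fold lower. BMP and SMAD1/5 targets had 0 of 18 members higher and 1 lower, with a median of 0.08 at percentile 78.8, and the BMP2 gene itself was at 1.42-fold.

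In all, 8364 genes were measured in WNT4 against GFP, with 475 at least 2-fold higher and 145 lower, or 5.68% and 1.73%. In the simulation for this comparison the rule named 2.94% of unchanged genes. Of 26 lists, 4 stood above and 7 below random lists, and the other 15 lay between percentiles 5.08 and 89.9. The 4 measured leukocyte and 4 measured endothelial markers each had 0 members 2-fold different.

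BMP2 and WNT4 were then compared with each other. Every one of the 23 measured DNA replication genes was at least 2-fold lower on the BMP2 array, with a median of -3.23 at percentile 0, and RRM2 was at least 94.0-fold, PCLAF at least 88.6-fold and TYMS 52.4-fold lower. Of 28 mitosis genes 21 were lower, with a median of -1.95 at percentile 0. BMP targets were higher in 15 of 20 members, with a median of 1.93 at the 100th percentile. ACTC1 was 91.4-fold higher on the BMP2 array, PLN 67.8-fold, FRZB 45.3-fold, HEY1 42.2-fold, NAV2 39.3-fold and STMN2 36.7-fold. HSD17B2 was at least 54.9-fold, PSAT1 at least 47.4-fold and MEST 38.1-fold lower. Interferon genes were lower on the BMP2 array in 14 of 28 members and higher in 2, IFI6 and IFI27, with a median of -1.04 at percentile 0.01. Decidualization markers had a median of 0.40 (percentile 98.6), a placing that was lost after median scaling (percentile 94.7). Of 14 members 5 were higher, among them CEBPB and TIMP3 at 2.08- and 4.38-fold, and 4 lower, among them IGFBP1 and DCN at 6.82- and 4.60-fold. The 4 include FOXO1, which was 5.25-fold lower by 1 probe set and 8.03-fold higher by the other. Without FOXO1 and the transgenes, 4 of 11 were higher and 3 lower, with a median of 0.60 at percentile 99.6.

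Pericyte and smooth muscle markers were higher in 5 of 10 members and lower in 1, KCNJ8 (median 1.1996, percentile 100). Inflammatory genes were lower (median -1.22, percentile 0.27), with ICAM1 14.0-fold and CCL2 11.9-fold lower. Of 17 inflammatory genes 10 were lower and 3, IL1R1, TNFAIP3 and IL11, higher, and the placing was lost under 2 of 8 alternatives, up to percentile 9.45. Matrix genes (median -0.32, percentile 1.27) and stress genes (median -0.60, percentile 0.56) also stood below random lists, and did so under all 8 alternatives. Their medians turned positive, at 0.33 and 0.05, after median scaling, which moved the median of all genes from -0.15 to 0.48. Here 8338 genes were measured, with 949 at least 2-fold higher on the BMP2 array and 1596 lower. The split depended on the scaling, with 2433 higher and 723 lower after median scaling and 1239 and 1100 after quantile normalization. Of 26 lists 9 stood apart, 3 above and 6 below, and the other 17 lay between percentiles 8.63 and 96.6. The loss of 5' signal on the BMP2 array enters this comparison as it does that with GFP.

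The last comparison asks how far the responses to BMP2 and WNT4 were shared. Shared genes cannot show whether WNT4 acts downstream of BMP2. The WNT4 probe set lay under the floor on the BMP2 array (6.93) and the GFP array (7.30), so no rise of WNT4 with BMP2 was seen. This probe set read only 31.7 on the WNT4 array itself, so it may miss a rise and decides nothing here. Among 8006 genes measured in both comparisons with GFP, 51 were higher and 49 lower than GFP on both the BMP2 and the WNT4 array. Independent lists of these sizes would share 33.5 and 18.7. Of the 51 genes, 12 belonged to the interferon list. The 51 include FOXO1, which is shared by 1 probe set only, and 50 genes remain without it. By the smaller of both differences, the highest of these were IFI44L (at least 7.67- and 13.2-fold), HERC5 (at least 6.35- and 24.0-fold), MCTP1 (10.5- and 4.69-fold), the neuronal enolase ENO2 (5.71- and 4.36-fold), ISG15 (4.07- and 5.16-fold) and OAS1 (3.79- and 11.3-fold). The lowest were PSG6 (9.82- and 4.01-fold), B3GALT2 (at least 3.43-fold on both), KRT19 (64.5- and 3.32-fold), CTF1 (3.13- and 3.17-fold), PADI2 (at least 4.49- and 3.11-fold) and SERPINB7 (at least 3.04-fold on both).

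Cell cycle genes called on both arrays mostly moved apart. Of 75 genes lower with BMP2 and higher with WNT4, against 50.7 for independent lists, 17 belonged to the replication or mitosis lists, as did 1 of the 49 lower and 0 of the 51 higher in both. A further 23 were higher with BMP2 and lower with WNT4, against 12.3. Over all 8006 genes the differences correlated at r = 0.01, with a covariance of 0.01. Both comparisons use the same GFP array, which makes them correlate by chance. In 100 simulations of 3 unchanged arrays the mean correlation was 0.50, the mean covariance 0.51, and 523 genes were higher and 557 lower in both. A correlation near 0.50 follows from the shared array when all 3 arrays carry equal noise, as simulated here. In the data, probe sets of 1 gene spread by an SD of 0.72 for BMP2 against GFP and 0.31 for WNT4 against GFP. The simulated noise was taken from BMP2 minus WNT4, which holds real effects, so the simulated covariance and counts may be too high. With 1 control array it could not be split, and how much of the excess over independent lists is due to the shared array is unknown. Genes moving in opposite directions exceeded independent lists as well, at 75 against 50.7 and 23 against 12.3. The excess of genes moving the same way thus does not by itself show a shared response. Genes are not independent replicates.

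**Figure D3:**
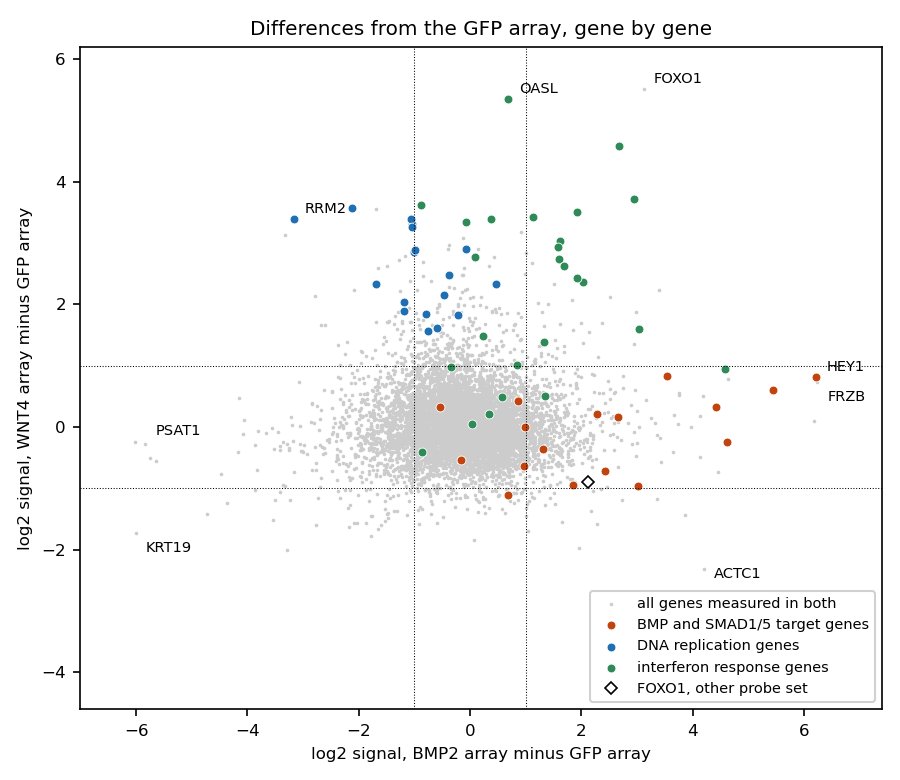
Each point is a gene measured in both comparisons, with its log2 difference from GFP on the BMP2 array (x axis) and on the WNT4 array (y axis), and dotted lines mark 2-fold. BMP targets spread along the x axis. Most DNA replication genes lie at the top left and most interferon genes at the top right. The probe sets of FOXO1 lie at 5.51 and -0.89 on the y axis.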

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

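Signals of control probe sets, which enter none of the comparisons, stood out on the BMP2 array. The test on added bacterial transcripts was chosen after the result was seen, and the other tests here were planned before theirs. Labelling starts at the 3' end, so the ratio of 3' to 5' signal grows when labelled products are short. On the BMP2 array this ratio was 5.91 for ACTB (1.12 on the GFP array), 185 for STAT1 (9.64), 14.3 for the bacterial control dap (1.49), 27.7 for thr (1.49) and 3.13 for phe (1.11), each at least 2-fold above the GFP array. Probe sets for 18S ribosomal RNA were also brighter there, at 180 for its 3' part, 141 for the middle and 169 for the 5' part, against 59.8, 28.6 and 43.9 on the GFP array. The cause of the ribosomal signal was not tested.

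Degradation of the cells' own RNA is argued against as the whole cause of the lost 5' signal, because transcripts added from outside lost it too. The mean log2 ratio of 5' to 3' signal of dap and thr was lower by 3.74 on the BMP2 array (a difference of -3.74). The bacterial controls phe and lys lost less. Their ratios of 3' to 5' signal were 3.13 and 1.30 on the BMP2 array, against 1.11 and 0.80 on the GFP array. Short products from the labelling of this sample stay open. They may also lower genes. Of the genes at least 2-fold lower on the BMP2 array, 35.0% had another probe set that was not lower, below the 51.1% with a disagreeing probe set among the higher genes. That outcome had been set beforehand as evidence against short products, and on seeing the data this reading was judged wrong: other probe sets may lie further 5' and would then be lowered with the first, and probe sets of 1 gene spread by an SD of 0.72 in log2 in BMP2 against GFP and 0.31 in WNT4 against GFP. So short products cannot be told apart from lower expression for the lower genes as a set. The genes called higher are not free of doubt either, as 51.1% of the 272 examined had a disagreeing probe set. Their count was 727 as deposited and 392 after scaling to the hybridization controls.

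The count of lower genes depends on the array scaling, but no scaling tried removed them. At least 482 genes, which need not be the same ones, were lower under each, above the WNT4 counts under the same scalings. That outcome had been set beforehand as evidence against scaling. The differences from GFP spread more widely for BMP2, with an SD over genes of 0.93 against 0.59 for WNT4. A wider spread gives more lower genes under any scaling, so these counts cannot exclude scaling together with noise. For the mitosis genes, with each gene at its least lowered probe set, a detail the plan had left open, the 7 members with several measured probe sets had a median of -0.88 at percentile 0.705 of random lists of such genes. This had also been set beforehand as evidence against short products. It decides nothing, because the other probe sets of a gene may lie further 5' and be lowered too. The random lists were matched on signal, not on probe position, only 7 of 28 members entered, and the placing of the whole list was lost (percentile 18.3) with the floor at the 60th percentile. So short products cannot be told apart from lower expression for the mitosis genes either.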

How the results depend on the processing

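The gene counts, the medians of the lists fixed before the data were examined and the values of named genes were recomputed under other choices. The further gene lists described among the other observations were not recomputed. Most of the choices were fixed in advance, and 3 were added after seeing the data. They were scaling to the hybridization controls, the count over genes with several probe sets and the decidualization markers without FOXO1 or the transgenes. Of the medians of gene lists, 407 stayed close, 204 moved and 6 changed sign, and of the values of named genes 3871 stayed close, 466 moved and 4 changed sign. A list median counts as close within 1 SD of the medians of its random lists, and a gene within the SD between probe sets of 1 gene. Over the 3 comparisons lists stood apart 29 times, and 16 of these placings held under all 8 scalings, floors and probe set choices. No paired analysis was possible because each group has 1 array, and the replicate number the arrays share is only a name. For the same reason leaving out a replicate was impossible, and leaving out the BMP2 array, whose 5' signal is in doubt, leaves no BMP2 comparison. A signal over background places bounds on genes near the floor. The cause of the changes below was not tested, except that a threshold or a floor changes a count by construction.

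The median difference over all measured genes was -0.09 for BMP2 against GFP, 0.02 for WNT4 against GFP and -0.15 for BMP2 against WNT4. It was 0.41, -0.11 and 0.48 after median scaling, 0.06, -0.02 and 0.06 after quantile normalization, and -0.41, -0.03 and -0.42 after scaling to the hybridization controls. Of the genes called, 41.4%, 76.6% and 37.3% were higher, against 79.6%, 63.0% and 77.1%, then 57.03%, 69.5% and 52.97%, then 17.6%, 72.2% and 19.9% under these scalings in the same order. So the main direction of the BMP2 array's differences depends on the scaling.

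Counts of genes are given here as higher and lower. Median scaling gave 1878 and 482 for BMP2 against GFP and 2433 and 723 for BMP2 against WNT4, and made the medians of matrix genes (0.33) and stress genes (0.054) positive in the latter, with the shift of all genes, while both lists kept their place below random lists. Scaling to the hybridization controls gave 392 and 1839 for BMP2 against GFP and 553 higher for BMP2 against WNT4. The floor at the 25th percentile gave 1644 lower for BMP2 against GFP, 825 and 366 for WNT4 against GFP and 118 and 192 shared by both. The floor at the 60th percentile gave 457 lower for BMP2 against GFP, 206 and 69 for WNT4 against GFP, 784 lower for BMP2 against WNT4 and 18 and 24 shared. Without a floor there were 1450 and 2803, 1528 and 964, 1612 and 3462 in the 3 comparisons and 481 and 492 shared. Without the probe sets that may bind several transcripts there were 470 and 595 for BMP2 against GFP, 285 higher for WNT4 against GFP, 934 lower for BMP2 against WNT4 and 27 shared higher. A threshold of 1.5-fold gave 1588 and 2094, 1169 and 681, 1810 and 2635, and 181 and 270 shared. A threshold of 3-fold gave 268 and 380, 188 and 11, 345 and 694, and 17 and 7 shared. Genes whose every probe set moved at least 2-fold the same way numbered 65 and 117, 62 and 11, 84 and 210, and 0 and 4 shared, among fewer genes. For BMP2 against GFP the median of the Wnt ligands, receptors and antagonists became -0.10 and -0.26 with the lower and the higher floor, -0.16 without one and -0.37 without the probe sets that may bind several transcripts, which also turned EBP to 0.42. With the mean of all probe sets, DUSP1 (-0.46), FOXO1 (0.31) and MET (-0.99) turned in BMP2 against WNT4.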

Other observations

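The gene lists and tests in this part were chosen after the result was seen, except the comparison of aminoacyl-tRNA synthetases, whose outcome was set down before it was computed. The lists of serine and proline synthesis, pregnancy-specific glycoprotein and cardiac genes were drawn up around genes already seen to differ, such as PSAT1, PHGDH, PSG6, PLN and ACTC1. These genes are counted, so the counts only describe and no percentile is given. Genes of amino acid synthesis were lower on the BMP2 array. Of 8 serine and proline synthesis genes, 7 were at least 2-fold lower than GFP and 0 higher, with a median of -2.61. PCK2, a mitochondrial enzyme of gluconeogenesis, was 9.07-fold lower, PYCR1 7.58-fold, ALDH18A1 4.89-fold and MTHFD2 4.45-fold. On the WNT4 array 0 of these 8 differed, with a median of -0.04. The ratio of 3' to 5' signal of ACTB was 5.91 on the BMP2 array.

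Of the pregnancy-specific glycoproteins, secreted proteins of the placenta, 7 of 7 measured members were at least 2-fold lower with BMP2 (median -3.33). With WNT4 3 of 7 were (median -0.96), and the other members were lower by less than 2-fold. Their sequences are nearly identical, so the members are not independent. Cardiac and smooth muscle genes were higher with BMP2 in 5 of 8 members (median 2.74), among them HOPX at 13.3-fold, TMOD1 at 6.68-fold and LDB3 at 6.63-fold. With WNT4 0 of 7 were higher and 2 lower, with a median of 0.04.

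A hypothesis was that lower activity of ATF4, which drives amino acid synthesis under stress, may lie behind the lower stress genes on the BMP2 array. Synthetases known as ATF4 targets should then lie at least 0.5 in log2 below the other cytosolic synthetases. The difference was -0.24, so the prediction was not met. The medians were -0.83 over 11 genes (5 lower, percentile 0.05) and -0.59 over 5 genes (1 lower, percentile 6.2). Probe sets of 1 gene spread by an SD of 0.72 in log2 in BMP2 against GFP. A difference of 0.5 between medians of so few genes may not be resolved, so lower ATF4 activity stays open. Both groups of synthetases lay near GFP on the WNT4 array, at -0.12 (percentile 26.8) and 0.22 (percentile 88.5).

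DNA replication genes on the WNT4 array were weighed against 4 explanations. Array scaling does not account for them, as their lowest median under the scalings tried was 2.72. More epithelial cells were weighed by the keratins, which are abundant in such cells. KRT7, KRT8, KRT18 and KRT19 were all lower, and the highest of their differences was -0.47. They were taken after the values had been seen, in place of the median of the epithelial list, whose members go both ways. KRT18 and KRT19 were already bright on the GFP array, at 1059 and 1321, and KRT7 lay near the floor on the WNT4 array, at 16.4. The keratins therefore need not follow the share of epithelial cells. EPCAM and SPINT1 were at least 3.20- and 2.46-fold higher, so such cells stay open. A larger or different viral load in the WNT4 culture is possible: early genes of adenovirus can drive cells into S phase, and interferon genes were lower on the BMP2 than on the WNT4 array, at a median of -1.04. This cannot be told apart from an effect of WNT4 without a viral transcript. Signalling through beta-catenin stays open as well. Its targets had a median of -0.29 (percentile 1.27), a placing lost under some alternatives. LEF1 was 3.24-fold higher, but it was also 3.99-fold higher on the BMP2 array, where replication genes were lower. For the interferon genes a low level on the GFP array alone would leave the BMP2 and WNT4 arrays equal. The median of BMP2 minus WNT4 lay -4.08 SD from that of random lists, so such a level does not account for the whole pattern. Random lists hold genes drawn independently and interferon genes can move together, so this distance can overstate the evidence. A low GFP level may still lie behind the rise on the BMP2 array.

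The probe sets of FOXO1 moved apart on the WNT4 array by 6.40 in log2. Disagreement of the size other genes show does not account for it, since the next gap was 2.59. A FOXO1 sequence carried by a virus, or RNA of another culture, may have been present on the array labelled WNT4. FOXO1 targets had a median of -0.36 there with IGFBP1 higher, so this cannot be told apart from a true change of 1 FOXO1 transcript form. The positions of the probes would be needed to decide.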
